A study of Drosophila melanogaster with 4 samples.

How the data were processed

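Hi-C, which joins DNA ends that lie close together in fixed nuclei and counts the joined pairs by sequencing, was run on salivary glands of male third-instar larvae of Drosophila melanogaster from a stock labelled yellow white. Larvae were grown at 25 °C and the glands were fixed with 2% paraformaldehyde, per the labels' protocols. Chromatin was cut with DpnII and the purified DNA was sheared to about 200 bp, per the labels' protocols. In 3 libraries, which the design text calls independent biological replicates, the ends were joined while the chromatin was held on beads (tethered). In 1 library the ends were joined in solution. Reads were aligned with Bowtie2 to genome build dm3, per the submitters' processing notes; the version, the read filters, the treatment of duplicate reads and the balancing software are not given in the sources used here. All coordinates are those of the files in dm3.

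The authors deposited 1 table per library and 2 merged tables of the tethered libraries, each listing pairs of bins with a contact signal. The deposited signal of the 3 tethered libraries and of the merged table in 15 kb bins was balanced, so that every bin's values sum to the same total, as found from the values themselves. The deposited signal of the in-solution library was not balanced and equalled whole contacts divided by a single constant. The merged table in 100 kb bins was not used here.

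Whole contacts per pair of 15 kb bins were recovered by finding a weight for each bin such that every value is a whole number times the weights of its bins. With a tolerance of 0.001, 100% of listed pairs came out whole in tethered replicates 1 and 2 and in solution, and 99.9% in tethered replicate 3. On contacts simulated over the pairs of the shallowest tethered library, 97.6% were recovered. The merged table equalled the sum of the 3 libraries in 98.6% of its pairs. In each library file no pair of bins on different arms held more than 1 contact. Chance alone at even coverage would give 3394, 2617 and 12 pairs with 2 or more contacts in tethered replicates 1 to 3 and 758 in solution. Contacts between arms are therefore capped in the files, and their share is a lower bound.

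Depth was 1926840 contacts in tethered replicate 1, 783638 in replicate 2, 191401 in replicate 3 and 328213 in solution. Confidence intervals of shares are 95% Wilson intervals. Intervals cover counting error only, since copies made by PCR are not independent molecules. Single values per library were compared by an exact two-sided permutation test of the group labels, 1 library against 3. It has 4 arrangements and cannot give a p below 0.25, so no call rests on it.

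The bin size of the files set the limits of distance. Short contacts are those in the same or a neighbouring bin, below 30 kb, and the slope of distance decay was fitted from 30 kb to 1 Mb on log10 scales. The alternatives planned at other limits moved to the nearest bin edges. Coverage is contact ends per length of arm relative to the autosomal arms 2L, 2R, 3L and 3R pooled. Expected contacts between arms come from the product of their contact ends, and arm ends are the outer 2 Mb. Boundaries are local minima of the log2 insulation score of the merged balanced 15 kb table, with a window of 150 kb and a prominence of at least 0.2. Windows in which fewer than a share of 0.7 of the bins held contacts were left out, and 0.02 was added to the scaled score before the log. Boundaries of 2 libraries within 1 bin were counted as shared and compared with 10000 circular shifts along each arm. The score was tested on data simulated at the depth of the merged table, with even coverage. On 4020 bins, 200 boundaries were planted evenly, with contacts across them lowered 3-fold and a spacing above the median domain length found here. Of these, 100% were found and 0 others were called. Closer or weaker boundaries and the depths of single libraries were not simulated. The plan had taken raw contacts as the main input and balancing as the alternative; the merged table came balanced, so their order was exchanged. Before the in-solution boundaries were called, that library was balanced by the same iterative correction. The same correction of recovered contacts gave r = 1.00 with the deposited values of tethered replicates 1 and 2 and r = 0.998 for replicate 3.

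Compartments are the first eigenvector of the correlation of distance-normalised contacts in 100 kb bins, per arm. Long range pairs are pairs of 100 kb bins at least 2 Mb apart or on different arms, with at least 1 expected contact. They were tested with a negative binomial model against the contacts expected from distance and coverage, with Benjamini-Hochberg adjustment at 0.05. For bins on different arms the pair of arms took the place of distance. A pair was called where it was also at least 2-fold above the expectation and above it in each of the 3 libraries. On 544312 simulated pairs, 24% of 200 pairs raised 4-fold passed the test and 27 of the 200 also passed the rule on single libraries, with 0 false calls. The simulated contacts were independent of each other (Poisson). False calls from many contacts gathered in a single pair of 15 kb bins could therefore not appear.

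The plan named edgeR's quasi-likelihood test for the comparisons of bins and of bin pairs, assuming a table of counts. The files hold a signal, so limma was used on log2 CPM of recovered contacts with the weights of voom, after filterByExpr and TMM scaling. Bin pairs were scaled to the tested within-arm pairs, not to all contacts of a library. This weighted form was chosen after limma without weights had been run on the real files. On simulated bin pairs, limma without weights called 115 unchanged pairs at a 2-fold change. Over 12 settings of its pseudocount and scaling it called 52 to 121, while limma with weights called 2 and edgeR 1. Without weights a pseudocount of 1 CPM was added. Both forms, edgeR and DESeq2 on the recovered contacts are reported. For 200 of 1204 bins changed 2-fold in simulated data, limma with weights called 83.5% and 2 unchanged bins. For 200 of 3130 bin pairs it called 11% at a 2-fold change and 69% at a 4-fold change, against 13% and 74% for edgeR. In these simulations all libraries were drawn from a single pooled profile with a fixed dispersion. Differences in profile between the real tethered libraries were not simulated, so these rates may not hold for the real data. The lone in-solution library is assumed to vary like the tethered ones.

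The rule for named regions was fixed before the data were examined: the 10 strongest boundaries, the 5 longest and 5 shortest domains, the 10 lowest and 10 highest bins in coverage among bins with at least 6 of their 15 kb bins, up to 5 called bins in each direction by size of change, up to 5 called bin pairs in each direction by adjusted p, and up to 10 called long range pairs. Of the lists of domains and of bins by coverage only the leading members are given. Alternatives covered replicates left out in turn, other distance limits, other windows, other tools, other filters and other bin sizes. Gene lists fixed before the data were examined were not used here, because no annotation of dm3 was given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.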

Results

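Polytene chromosomes of the larval salivary gland consist of many aligned copies of each chromatid. Their contacts were measured by Hi-C in 4 libraries of male third-instar glands, 3 ligated on beads (tethered replicates 1 to 3) and 1 ligated in solution. The libraries held 1926840, 783638 and 191401 contacts (tethered replicates 1 to 3) and 328213 contacts (in solution). The merged tethered table held 2919703 contacts.

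The first comparison asked how contacts made on beads and in solution were divided between chromosomes. Contacts between different chromosomes made up 20.4% ± 14.3 (SD, n = 3) of tethered contacts and 45.6% of contacts in solution (95% Wilson interval 45.4 to 45.8). Contacts between the arms of a chromosome made up 6.66% ± 3.33 (SD, n = 3) and 14.6%. Contacts within an arm at 30 kb or more made up 38.9% ± 7.39 (SD, n = 3) and 22.1%, and contacts in the same or neighbouring bins 34.0% ± 10.5 (SD, n = 3) and 17.7%. The in-solution library lay outside the tethered range in all 4 classes, and the exact permutation test gave p = 0.25 in each, the smallest that 1 library against 3 allows. The tethered libraries themselves ranged from 9.19% to 36.5% in contacts between chromosomes, with the highest share in replicate 2. In the files each pair of bins on different arms holds at most 1 contact per library, so the between-arm shares are lower bounds.

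**Figure D1:**
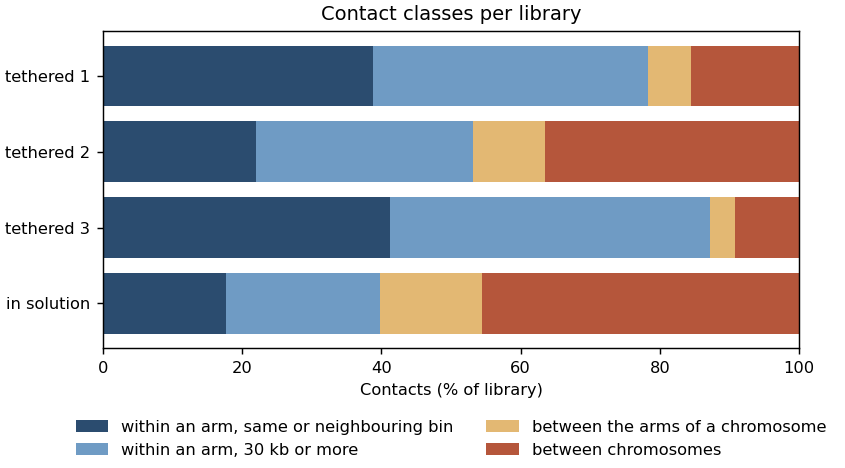
Share of contacts in 4 classes (percent of each library, horizontal bars) for the 3 tethered libraries and the in-solution library. Contacts between chromosomes take 45.6% in solution and 9.19% to 36.5% in the tethered libraries.

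Contact frequency within arms fell with distance in all 4 libraries. The slope from 30 kb to 1 Mb was -1.57 ± 0.208 (SD, n = 3) in the tethered libraries and -1.40 in solution, a difference of 0.169 that lay within the tethered spread (exact permutation p = 0.75). After the mean of bin pairs between arms was subtracted, a step chosen after the data were seen, the slopes were -1.62 ± 0.175 (SD, n = 3) and -1.86, so the direction of the difference turned. In the tethered libraries the slope of X differed from that of the autosomal arms by -0.0233 ± 0.0696 (SD, n = 3), less than its spread.

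**Figure D2:**
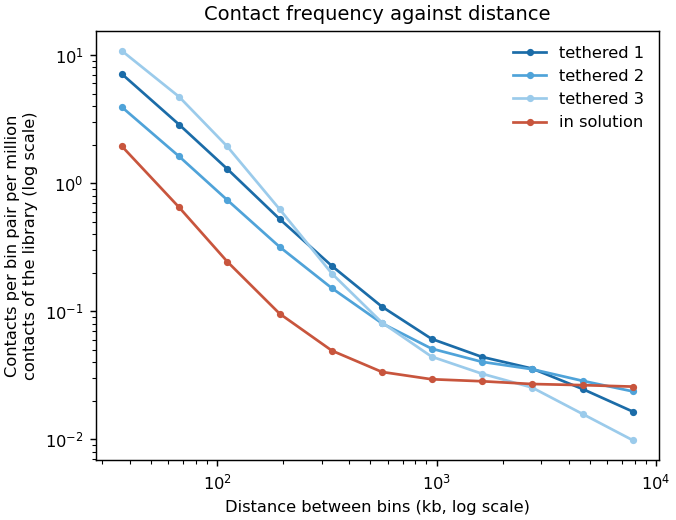
Contacts per pair of 15 kb bins, scaled to each library's total contacts (vertical, log scale), against the distance between bins in kb (horizontal, log scale), one line per library. The in-solution line lies below the tethered lines at 36.7 kb and flattens toward larger distances.

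The X chromosome, of which males carry a single copy, was covered less than the autosomal arms. Its coverage was 0.645 ± 0.121 (SD, n = 3) of theirs in the tethered libraries and 0.566 in solution (exact permutation p = 0.75). Within arms it was 0.587 ± 0.0537 (SD, n = 3), and between arms 0.741 ± 0.20 (SD, n = 3), where replicate 2 stood at 0.970. Chromosome 4 was covered at 0.688 ± 0.113 (SD, n = 3) and 0.616 in solution. Counted from between-arm contacts alone, a setting chosen after the data were seen, chromosome 4 reached 1.05.

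The 10 bins lowest in coverage lay on the centromeric sides of their arms, up to 2.2 Mb from the arm end. The bins X:21700001-21800000, with 0 contacts in every library, 3L:24400001-24500000, at 0.00815 ± 0.0141 (SD, n = 3), and 2L:21400001-21500000, at 0.0107 ± 0.0115 (SD, n = 3), were among them. The highest bin was 3R:5700001-5800000 at 1.75 ± 0.143 (SD, n = 3), against 0.827 in solution. Away from the arm ends, 22 regions covering 3.5 Mb fell below a share of 0.5 of their arm's mean. The region of 2L from 17000001 to 17300000 stood at 0.171 ± 0.0900 (SD, n = 3) of its arm's mean and at 0.0744 in solution. The region of 2L from 4500001 to 4700000 stood at 0.406 ± 0.00639 (SD, n = 3) in the tethered libraries and at 1.34 in solution.

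**Figure D3:**
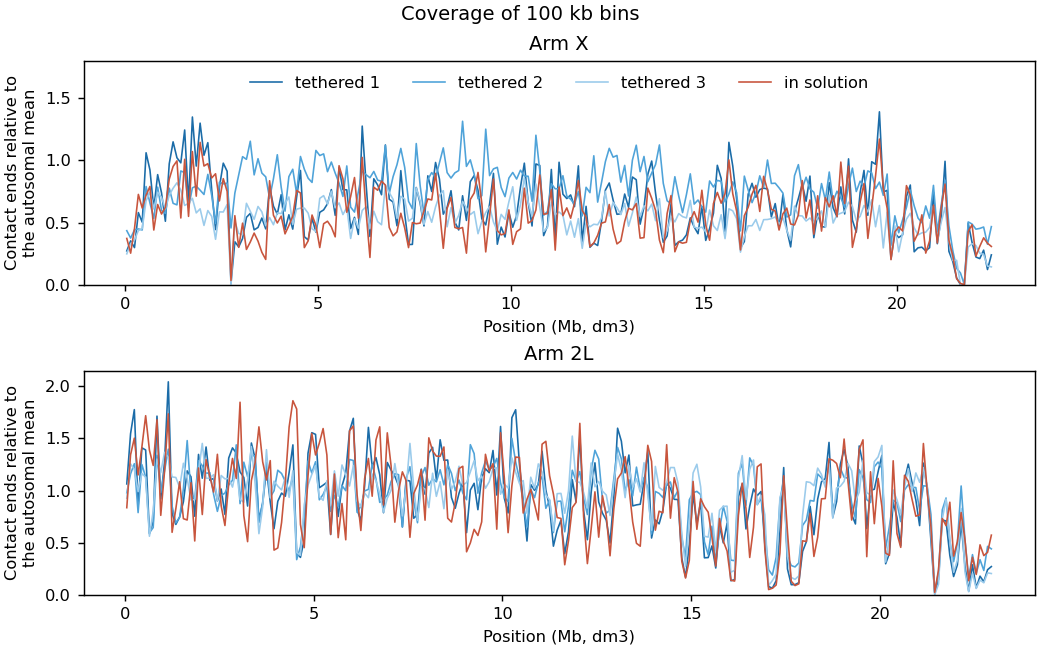
Contact ends per 100 kb bin relative to the autosomal mean (vertical) along arms X and 2L (horizontal, Mb in dm3), one line per library. Many bins near the centromeric end at the right lie low, and on X replicate 2 lies above the other libraries over most of the arm.

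Arms of the same chromosome met more often than arms of different chromosomes in the tethered libraries, by a ratio of observed over expected of 1.20 ± 0.102 (SD, n = 3), against 1.01 in solution. The ends of the arms showed a stronger pattern. Centromeric ends of different chromosomes met at 2.33 ± 0.411 (SD, n = 3) times the expected number and those of the same chromosome at 2.88 ± 0.589 (SD, n = 3), against 1.20 and 1.13 in solution. Telomeric ends met at 1.23 ± 0.0666 (SD, n = 3) and 1.30 ± 0.0630 (SD, n = 3), against 1.01 and 1.04. Centromeric with telomeric ends met less than expected, at 0.707 ± 0.164 (SD, n = 3) between different chromosomes and 0.627 ± 0.128 (SD, n = 3) within the same chromosome, against 1.01 and 1.03. The exact permutation test gave p = 0.25, the smallest possible, for the centromeric ends of different chromosomes and for the ratio of arms.

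**Figure D4:**
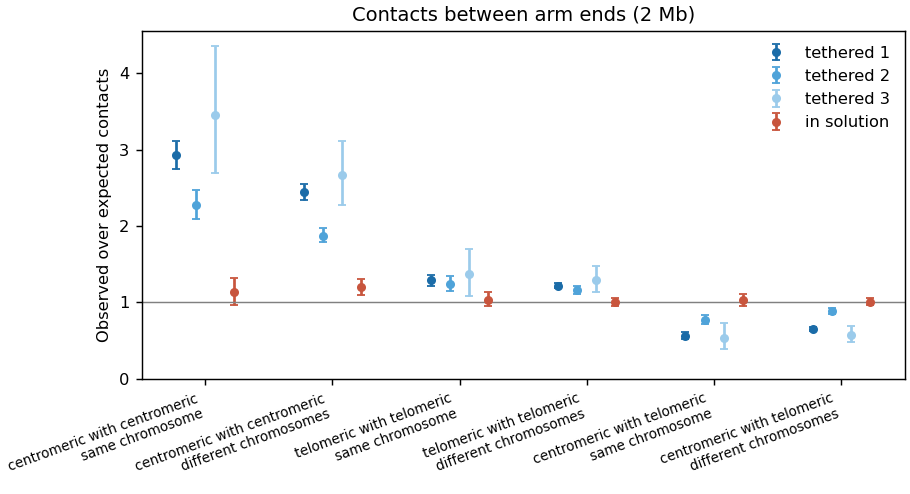
Observed over expected contacts (vertical) between the outer 2 Mb of arms, by kind of end and by same or different chromosomes; points are libraries and bars 95% counting intervals. All 3 tethered libraries lie above 1 for centromeric with centromeric ends, and in solution the points lie between 1.01 and 1.20.

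The merged tethered map divided into 622 boundaries with a median domain length of 165 kb, and 10% to 90% of domains lay between 60 and 345 kb. The strongest was at 3R:8295001, with a prominence of 2.56 on the log2 scale; it lies beside 2 bins without contacts, and 13 of the 622 boundaries had at least 1 such bin beside them. Among the 10 strongest were also 2L:6480001 (2.34), 3L:5745001 (2.11) and 2L:16860001 (2.09), each found in all 3 tethered libraries, and X:2850001 (2.08), found in replicate 2 alone. The remaining ones were 3L:9375001, 3L:13995001, 3R:2910001, 2L:12000001 and 2L:10260001, each found in all 3 tethered libraries. Beside X:2850001 lies the stretch from X:2730001 to X:2805000, in which replicates 1 and 3 held 0 contact ends. Too few bins of the 150 kb window held contacts there, so replicates 1 and 3 could not score that boundary. Of all boundaries, 323 were found in all 3 tethered libraries, 235 in 2, 58 in 1 and 6 in none. The merged table sums these libraries, so recurrence in them is partly built in. Shifted boundaries of replicate 1 also met one of replicate 2 in 34.1% of cases and one of replicate 3 in 36.3%. The longest domain was on 3R from 1605001 to 2205000 (600 kb), and the shortest measured 30 kb. X held 6.24 boundaries per Mb and the autosomal arms 5.12. Within single tethered libraries the ratio of these densities was 1.17 ± 0.0884 (SD, n = 3), and in solution it was 1.07. Libraries with fewer within-arm contacts gave more boundaries, as given below. X was also covered less than the autosomal arms, so its higher density was not separated from sparser contacts.

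Boundaries recurred between libraries. Tethered replicates 1 and 2 shared 436 of 630 boundaries, 2.03 times the mean of shifted sets, replicates 2 and 3 shared 1.55 times the shifted mean, and the in-solution library shared 1.47, 1.25 and 1.37 times the shifted mean with replicates 1 to 3. Each of these had a permutation p of 0.0001, the smallest that 10000 circular shifts can give. Contacts inside domains of the merged tethered table exceeded those across boundaries at the same distance by 2.20 ± 0.235 (SD, n = 3) in the tethered libraries and by 2.91 in solution. Calling boundaries at minima of contact builds the excess into the tethered value. The in-solution library took no part in calling these boundaries. Without balancing the in-solution value was 2.44, inside the tethered range of 1.82 to 2.58. The insulation score of replicate 1 at full depth correlated at r = 0.651 with the in-solution library, which held 41244 contacts within reach of the score. Thinned to that number, replicate 2 gave r = 0.304 and replicate 3 gave 0.639 with replicate 1. With all their contacts these values were 0.515 and 0.808. The in-solution library gave 1577 boundaries from 130660 within-arm contacts. Tethered replicates 1 to 3 gave 630, 925 and 996 boundaries from 1509470, 417043 and 166842 such contacts. Without balancing, 57.1% of the 622 boundaries were found.

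**Figure D5:**
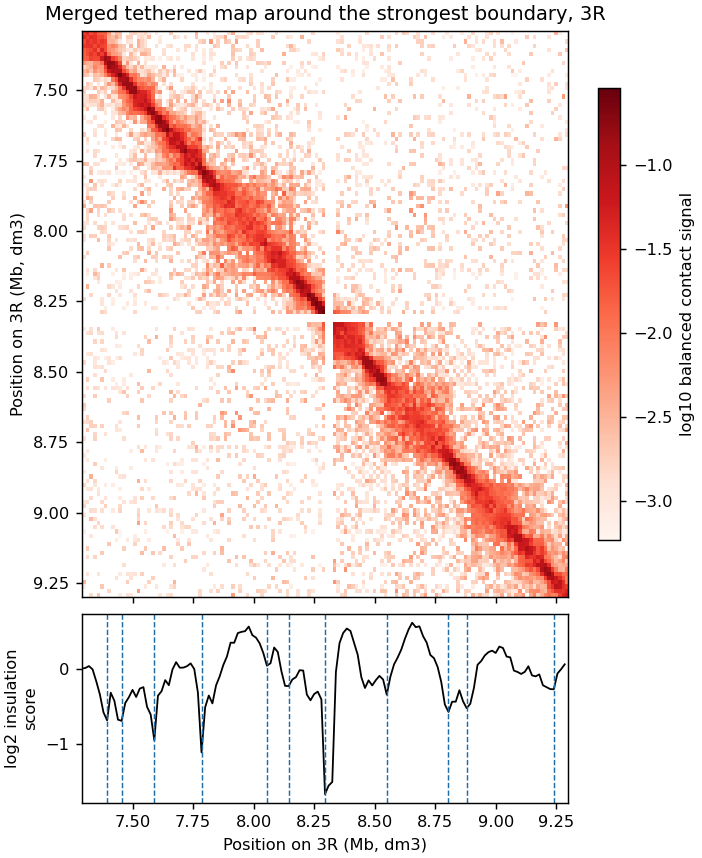
Balanced contact signal (colour, log10) between 15 kb bins of 3R from 7.29 to 9.3 Mb in the merged tethered table, above its log2 insulation score (line) with called boundaries (dashed). The deepest minimum is the boundary at 8.295 Mb, and the white cross beside it marks bins without contacts.

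The first eigenvectors of tethered replicates 1 and 2 correlated with a mean absolute r of 0.0664 over 5 arms in 100 kb bins, not above the 95th percentile of 0.0881 in shifted eigenvectors (mean 0.0547). In 200 kb bins the mean was 0.202, above the shifted 95th percentile of 0.131. Bins of the same class in replicate 1 met each other in replicate 2 at 1.13 times the rate of bins of opposite class, above the highest value of 1.03 among 200 shifts, a test chosen after the data were seen. On X that value was 0.984. In solution it fell below 1 on every arm but X, with the lowest at 0.947.

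In single bins, 20 of 1204 bins of 100 kb were covered more in solution than in the tethered libraries, and 0 less, with limma at an adjusted p under 0.05. The bin at 2L from 4500001 to 4600000 differed most, by 2.22 on the log2 scale (SE 0.149, limma adjusted p = 0.000748). Next came 3R from 17200001 to 17300000 at 1.31, 2L from 600001 to 700000 at 1.27, 2L from 3500001 to 3600000 at 1.26 and 2R from 18700001 to 18800000 at 1.25. At an unadjusted p under 0.05 there were 252 bins. The number and direction of calls depended on the libraries and the tool: leaving out replicate 1 gave 620 bins (352 higher, 268 lower), leaving out replicate 2 gave 281 (150 and 131), leaving out replicate 3 gave 69, and edgeR gave 192 (74 and 118).

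Among pairs of 100 kb bins within arms, 95 of 3130 were higher in solution relative to the tested pairs and 0 lower, with limma, and 602 had an unadjusted p under 0.05. The tested pairs held 75480 of the 328213 contacts in solution and 34.8% to 75.5% of contacts in the tethered libraries. Scaled to all contacts of each library, a setting chosen after the data were seen, 4 pairs were higher and 595 lower, and 4 of the 95 calls stayed. Of the 95, 78 were pairs of a bin with itself. Relative to the tested pairs, contacts within the bin 2L 4500001 to 4600000 differed by 4.93 on the log2 scale (SE 0.574, limma adjusted p = 0.00624), with 120 contacts in solution and 110, 19 and 2 in tethered replicates 1 to 3. That bin and its neighbour from 4400001 differed by 3.92, and contacts within 2L 13900001 to 14000000, 2L 600001 to 700000 and 2R 200001 to 300000 differed by 3.27, 3.18 and 3.74. Scaled to all contacts these 5 values were 3.79, 2.42, 1.68, 1.58 and 2.18, and only the first passed. Scaled within each distance, 7 pairs were called. Leaving out replicate 1, 2 or 3 gave 168 (117 higher, 51 lower), 34 (28 and 6) or 546 pairs (509 and 37); edgeR gave 80 higher and 5 lower, and with no filter on low contacts all 325 calls were lower.

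Of 545481 pairs of bins tested for long range contacts, 25 passed the test and the 2-fold limit, and 5 of them were also above the expected number in each tethered library. An unadjusted p under 0.05 was found for 15599. In replicate 3 the 5 held only 1 or 2 contacts each. The highest of the 25, 3R 3800001 with 3R 17500001 at 41.7 times the expected contacts, was not called. It held 29, 34 and 0 contacts in replicates 1 to 3, and 25 of its 63 contacts fell in 1 pair of 15 kb bins of 1 library. Of the 5, 4 lay on the same arm, such as X 3500001 to 3600000 with X 6200001 to 6300000 at 20.6 times the expected contacts. In that pair 44 of 49 contacts came from a single pair of 15 kb bins in replicate 1. The others on the same arm were X 7900001 with X 13800001 at 8.08, 2R 6900001 with 2R 14600001 at 5.94 and 3R 14100001 with 3R 22000001 at 5.07 times the expected contacts, each given by the starts of its bins. The fifth joined 2L 20400001 to 20500000 with 2R 1800001 to 1900000, on either side of the centromere. It held 13 contacts, 7.92 times the expected number. Between arms that expectation holds no term for position along the arm, so a general excess near centromeres was not taken out. All 3 pairs between arms past the test joined the centromeric sides of 2L and 2R. Between arms a 15 kb pair holds at most 1 contact per library, so the contacts of the fifth could not gather in 1 such pair of a library. In 3 of the 5, over 50% of the contacts fell in 1 pair of 15 kb bins of 1 library. With each 15 kb pair counted once per library only the fifth stayed called. Single counting could not lower the contacts of the fifth, so it is no check of that pair. Without replicate 1 there was 1 call and without replicate 3 there were 21.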

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

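All tests below were chosen after the results were seen, except the thinning of tethered replicate 1. In 1 of the 4 libraries, tethered replicate 2, the deposited table lists 27 pairs of mitochondrial with nuclear bins, and the other 3 list 0; mitochondrial pairs enter no comparison.

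Tethered replicate 2 stood apart on X, with a between-arm coverage of 0.970 against 0.640 and 0.611 in replicates 1 and 3. An interval was then chosen as the longest inner run of X bins nearly empty in replicates 1 and 3 and with contacts in replicate 2. Over these 75 kb, from X:2730001 to X:2805000, replicate 2 held 525 contact ends, replicates 1 and 3 held 0 and the in-solution library 15. The choice fixes the direction of this contrast between the tethered libraries. The unbalanced in-solution file was nearly empty there, at 0.0335 of autosomal coverage, which argues against the balancing as the cause; between-arm ends drawn as in that library would place 22.3 ends there (up to 38.9 by counting) against 442 seen between arms, which argues against more chance ligation of such DNA. From between-arm coverage, a share of 98.8% of mixed-in DNA carrying the interval was read. The reading used the gap between X, at 0.970, and the interval, at 0.963, in replicate 2. This gap was set against X at 0.626 in replicates 1 and 3. No counting error was computed for the share. At that share the between-arm coverage of 19 low autosomal regions was expected to rise to 0.993. These stood at 0.539 ± 0.113 (SD over regions), against 0.466 in replicates 1 and 3, so this prediction failed. Within arms the interval stood at 0.147, and no prediction was made from that value. Coverage of the interval over its flanks, within arms over between arms, was 0.420 in replicate 2 (counting interval 0.324 to 0.546), below the lowest 1% of 1204 other X windows (0.439) by less than its counting error, so a library wholly from another stock stays open. Mixed-in DNA at a lower share, or that itself has the low regions, was not tested and stays open, and no biological explanation was tested.

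In solution, arm ends met near the expected number. Tethered replicate 1 thinned to the same number of between-arm contacts still gave 2.46 for centromeric ends of different chromosomes (lowest of 20 draws 2.34), against 1.20 in solution, which argues against depth. At most 14.9% of the tethered excess was kept in solution over 5 measures, which restates the pattern and decides nothing about chance ligation between fragments. With 1 in-solution library, chance ligation and another difference of that library cannot be told apart.

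Of the 25 long range pairs past the test, 19 had most of their contacts in a single pair of 15 kb bins of 1 library. In 12 of these 19 the contacts of replicates 1 and 2 departed from those libraries' contacts at 2 Mb or more (Fisher's exact test, adjusted), a test that takes contacts as independent, and 8 were seen in 1 tethered library only, against the presence in proportion to depth that a fixed difference would give if no contacts were copies. The 8 surrounding pairs held a median of 2.17% of the contacts, a low share that the choice of these pairs fixes. Of the 19, 4 were also seen in solution. Over the 19 as a set, a fixed difference of the stock, a repeated sequence and copies of the same ligation product therefore cannot be told apart. No biological explanation was tested.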

How the results depend on the processing

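Background subtraction, coverage by kind of contact, arm ends of other lengths, edgeR, limma without weights, scaling to all contacts and single counting of 15 kb pairs were chosen after the data were seen. Of 99 alternative values over 17 results, 67 stayed within the spread or within 1.5 times the count, 29 moved and 3 reversed. The cause was not tested unless given. Some of the 67 could not move. The limit of short contacts does not enter the share between chromosomes, and compartment r without replicate 3 is the main value itself. Bins tested without the filter were the same 1204. Boundaries without balancing stayed close in number, at 632, though only 57.1% of the 622 were found. The difference in slope of 0.169 became -0.123 over a nearer range, 0.448 over a farther range and -0.232 after subtraction, and without replicate 1, 2 or 3 it was 0.195, 0.257 or 0.0540, each within the tethered spread of the main value. Chromosome 4 coverage in the tethered libraries became 0.547 within arms and 1.05 between arms. The within-arm share at 30 kb or more differed by -26.5 points with same-bin contacts alone as short and by -8.22 with a longer limit, since the class itself changes. Centromeric ends of different chromosomes gave 3.19 for ends of 1 Mb and 1.89 for ends of 3 Mb. Bins called, 20, became 69 to 620 with a replicate left out, 296 with DESeq2 (123 higher, 173 lower), 192 with edgeR, 201 without weights (68 higher, 133 lower) and 212 (203 higher, 9 lower) in 45 kb bins. Bin pairs called, 95, became 34 to 546 with a replicate left out, 169 with DESeq2 (161 higher, 8 lower), 685 without weights (220 higher, 465 lower), 325 without the filter (0 higher), 7 with scaling within each distance and 599 (4 higher, 595 lower) with scaling to all contacts of each library. Boundaries fell to 370 with a median domain of 285 kb at the stricter prominence, and sharing of tethered replicates 1 and 2 rose to 3.33 times the shifted mean in the same bin. Compartment r became 0.202 in larger bins. Long range calls, 5, became 1 to 21 with a replicate left out, 9 with a Poisson model and 1 with each 15 kb pair counted once. That 1 lies between arms, where single counting changes nothing. Tethered replicate 3, with 191401 contacts, limits the calls that need every library. Counting identical positions once, leaving out contacts under 1 kb and the gene lists were not run, because the files hold binned contacts and no dm3 annotation was given. No paired analysis was possible because the title of the in-solution library names no matching tethered replicate.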

Other observations

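The 22 low inner regions were chosen by the tethered mean. In 16 of them all 3 tethered libraries lay below 0.5 of the arm's mean, and in 19 the in-solution library did. On X from 2700001 to 2800000 replicate 2 stood at 0.554 and replicate 3 at 0. Averaged over the 22 regions, coverage relative to the arm was 0.278 in tethered replicate 1, 0.415 in replicate 2, 0.346 in replicate 3 and 0.384 in solution, and replicate 2 was the highest of the tethered libraries in 18 of them. In 21 of the 22 the in-solution library also lay below its arm's mean. The exception was 2L from 4500001 to 4700000.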
